A study of Mus musculus with 7 samples.

How the data were processed

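RNA was measured in macrophages sorted from MC38 tumours (a mouse colon carcinoma line) of high-fat-diet-fed mice, 21 days after the tumour cells were implanted. The sorted cells were positive for CD45, CD11b and F4/80. Each of the 7 libraries came from a separate mouse, 4 wild-type and 3 Gpr65 knockout. Per the labels' protocols, polyA RNA was made into libraries with a SMART-seq kit. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an antisense partner were not told apart.

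The authors deposited a table of read counts per gene, with whole numbers that sum to between 22449772 and 30483733 per library, so the values are raw counts without normalization. Per the submitters' processing notes, the tools included cutadapt 1.15, FastQC 0.11.5, BWA 0.7.12 and DESeq2 1.24.0, and the genome build was GRCm38. The notes give these tools no role or order, and the program that assigned reads to genes is not given in the sources used here. An aligner that does not split reads over introns would lose some reads at exon junctions, and the effect of this on the counts was not tested.

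Genes were named by Ensembl identifier from the GENCODE M21 annotation of GRCm38, because some symbols in the deposited table were older synonyms of other genes. Of 53379 identifiers, 53274 matched (99.8%) and 1319 symbols differed from the table, while the 105 unmatched identifiers kept the table's symbol. Rows without a symbol held 0.000338% of the counts and were kept under their identifier.

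The comparison was fitted with edgeR 4.0.16 under R 4.3.3, using the quasi-likelihood F test with robust estimation, TMM scaling, the default filter on low counts by group, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 16234 genes, and 24377 genes of the table had 0 counts in all libraries. The model held an intercept and the genotype, with all 7 libraries. Values per library are TMM-scaled CPM of the deposited counts, and log2 CPM used a prior count of 2. Fold changes are knockout minus wild-type on the log2 scale, with a standard error (SE) derived from the fold change and its F statistic.

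Before the data were examined, 48 gene lists were written, 26 on biology, 18 on cell types, some of which the sort should remove, and 4 on RNA quality. Lists with at least 4 tested genes, 41 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. A list score is the mean log2 CPM of the list's genes in a library. Aldolase A has more than 1 identifier under its symbol, so the glycolysis list of 19 symbols held 20 tested genes. Scores and library measures were compared by a two-sided exact permutation test over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0286.

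Named genes followed a rule fixed before the data were examined. It takes Gpr65, and, with fewer than 10 genes past the threshold, the 10 genes higher and the 10 lower with the smallest unadjusted p, an average log2 CPM of at least 1 and no overlap between the groups, leaving out unnamed gene models, pseudogenes, Y-linked genes, Xist and receptor segments. It adds up to 4 members of each biology list past the threshold, or the 2 highest-expressed members where none passed. Other genes named in the text were chosen after their values were seen. The result of 1 gene is not reported here.

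The test was tried on simulated counts for the 16234 tested genes with 200 changed genes. It recovered 9 of 100 genes changed 2-fold and 57 of 100 changed 4-fold, each in the right direction, with 3 false calls among 69. In a second simulation of 41 unchanged lists of 15 independent genes, camera called 0, and it called a list shifted 1.5-fold. Genes of the real lists were correlated, with an estimated 0.44 for interferon-stimulated and 0.85 for MHC class II genes. The simulation therefore does not give the rate of false calls for such lists. Between mice the common biological coefficient of variation was 42.9%.

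The alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma voom with library weights, edgeR without robust estimation, the mouse number as a block, each library left out in turn, an adjusted p of 0.1, and for the lists an estimated correlation and fry. Pairs of libraries of the same group differed far beyond sampling noise, so none was treated as a repeat of another.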

Results

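The series profiled tumour-associated macrophages of high-fat-diet-fed mice and compared 4 wild-type with 3 knockout mice for Gpr65, a receptor that senses extracellular protons. The total count was 22449772, 27600735, 28024612 and 25849769 in wild-type mice 1 to 4, and 26253675, 30483733 and 28174421 in knockout mice 1 to 3. Between 18276 and 23163 genes had at least 1 count per library, with the lowest number in knockout 1 and the highest in knockout 2.

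Gpr65 (chromosome 12, 98268635 to 98276644, plus strand, GRCm38) was lower in each knockout library than in each wild-type library. It measured 90.9 ± 19.4 CPM (SD, n = 4) in wild-type mice and 0.921 ± 0.215 CPM (SD, n = 3) in knockout mice, which was 1.01% of the wild-type mean. The counts were 1785 to 2912 in wild-type and 20 to 30 in knockout libraries. The log2 fold change was -6.62 (SE 0.30, edgeR adjusted p = 8e-05), and the exact permutation p of 0.0286 was the smallest that the 35 splits can give. A count per gene does not show which part of Gpr65 the remaining reads came from.

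The question of the series is how the absence of Gpr65 alters these macrophages. Besides Gpr65, 3 members of the Schlafen family and Wdfy1 were higher in knockout macrophages and the noncoding transcript AA465934 was lower. Slfn9 rose from 1.11 ± 0.378 CPM (SD, n = 4) to 27.8 ± 6.23 CPM (SD, n = 3), a fitted 24.8-fold difference. Slfn5 rose from 10.6 ± 2.87 to 65.5 ± 18.0 CPM, and Wdfy1, which encodes an endosomal FYVE-domain protein, from 13.9 ± 1.18 to 62.1 ± 7.13 CPM. Slfn2 had 0 counts in all 4 wild-type libraries and 19.3 ± 4.32 CPM in knockout libraries, at least 692-fold higher against a floor of 3 counts over the wild-type group, for counting error only. AA465934 fell from 5.73 ± 1.68 to 0.362 ± 0.142 CPM.

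**Figure D1:**
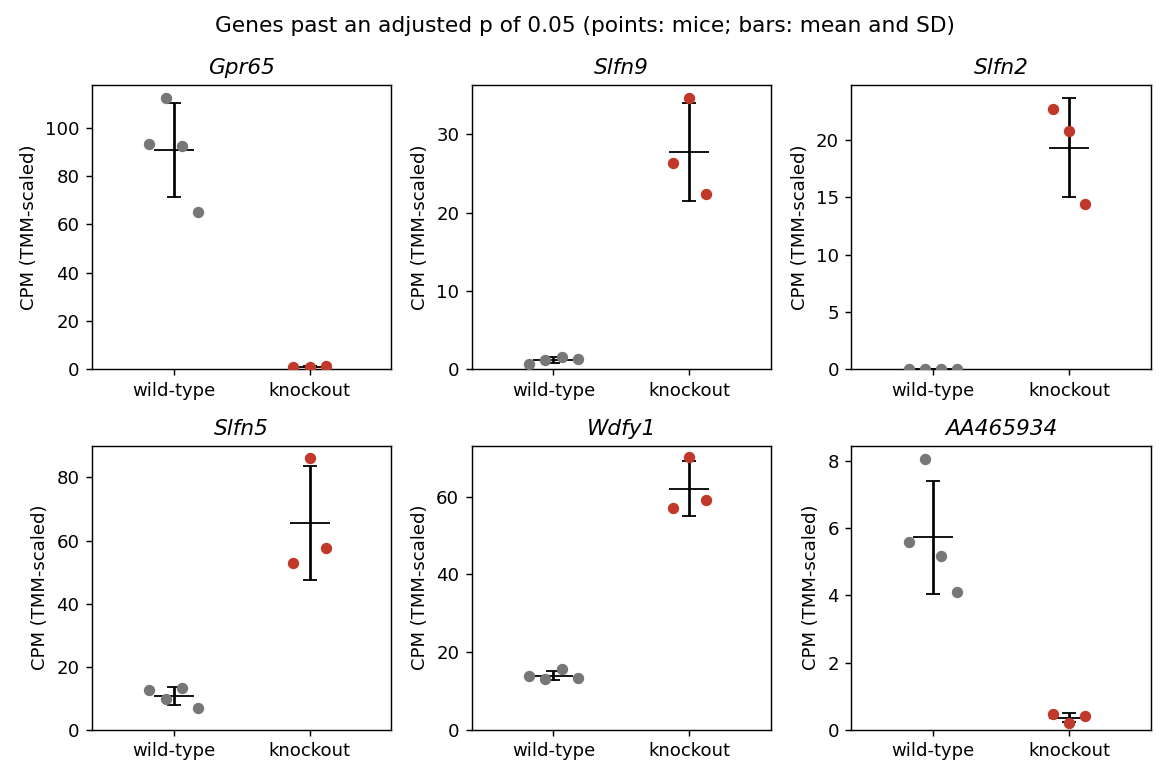
TMM-scaled CPM of the 6 genes past an adjusted p of 0.05, with a point for each mouse (4 wild-type in grey, 3 knockout in red) and bars for the mean and SD. In each panel the groups do not overlap, and Slfn2 lies at 0 in the 4 wild-type mice.

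Among 16234 genes tested, edgeR called these 6, 4 higher and 2 lower. The log2 fold changes were 4.63 (SE 0.34, adjusted p = 0.0016) for Slfn9, 2.16 (SE 0.16, adjusted p = 0.0016) for Wdfy1 and 2.63 (SE 0.27, adjusted p = 0.016) for Slfn5. AA465934 had -3.96 (SE 0.48, adjusted p = 0.048), and Slfn2 an adjusted p of 0.0035. At an unadjusted p under 0.05 there were 418 genes higher and 453 lower, and 994 genes (6.12%) had groups that did not overlap, where chance gives 5.71%. DESeq2 called 114 genes, 43 higher and 71 lower, among them the 6. Without knockout 1 edgeR called 14 genes and without knockout 2 it called 3. The adjusted p of Slfn2 was 0.072 without knockout 2, that of Slfn5 was 0.067, 0.12, 0.099 and 0.071 without wild-type 1, wild-type 2, knockout 2 and knockout 3, and that of AA465934 lay between 0.12 and 0.26 without any one library other than knockout 1, between 0.053 and 0.066 under 3 other scalings, and at 0.11 by limma voom.

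Slfn5 (82951349 to 82964840), Slfn9 (82978390 to 82991830), Slfn2 (83065112 to 83070678) and AA465934 (83291699 to 83294632) lie together on chromosome 11, and Wdfy1 lies on chromosome 1 (79702262 to 79776143), where it overlaps 2 genes of the opposite strand that held 3876 counts over all libraries. Between 4.27% and 11.2% of the 50-base words of Slfn2, Slfn5 and Slfn9 transcripts also occur in transcripts of other Slfn genes, and reads from these words cannot be assigned to 1 gene. The summed CPM of the 10 genes with a Slfn symbol, pseudogene and antisense gene included, was 34.8 ± 7.04 (SD, n = 4) in wild-type and 128 ± 25.2 (SD, n = 3) in knockout mice (exact permutation p = 0.0286). Slfn1, Slfn8 and Slfn14 had 0 counts in all libraries. Slfn4 measured 22.6 ± 5.14 CPM (SD, n = 4) in wild-type mice and 36.0, 4.64 and 4.37 CPM in knockout mice 1 to 3, and did not pass, although it was called lower without knockout 1. The chemokine genes Ccl4 and Ccl3, from the same part of the chromosome, had log2 fold changes of 2.00 (SE 0.28, edgeR adjusted p = 0.14) and 1.52 (SE 0.22, adjusted p = 0.14) and did not pass the threshold. Each knockout mouse lay above each wild-type mouse, which the rule that named these 2 genes required.

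**Figure D2:**
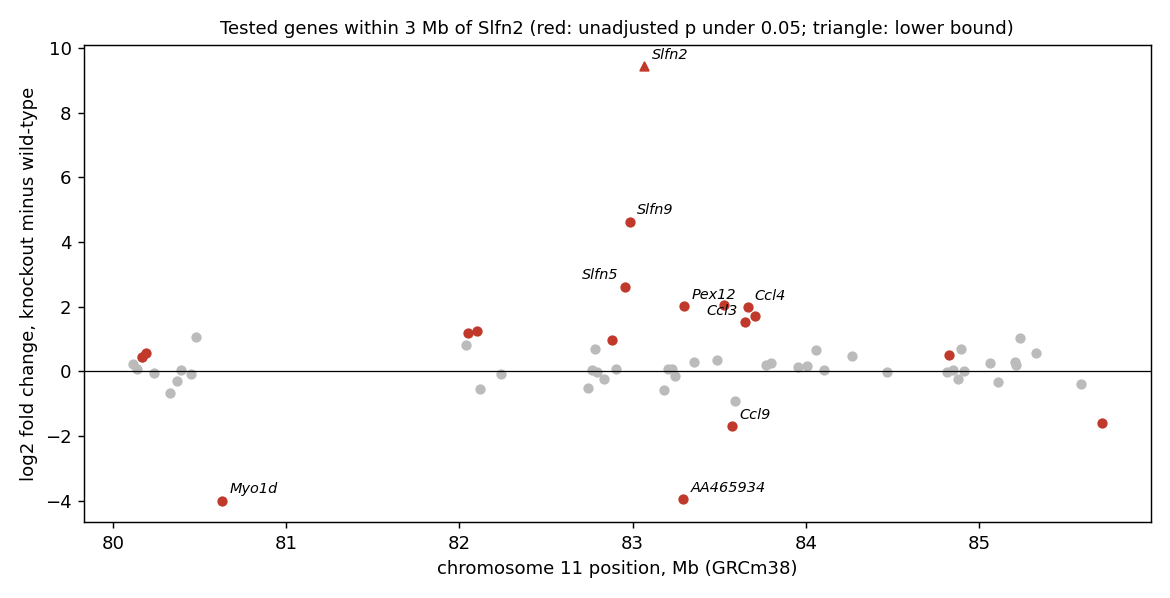
Log2 fold change, knockout minus wild-type, of the 63 tested genes within 3 Mb of Slfn2 against their position in Mb (GRCm38), with the 18 genes at an unadjusted p under 0.05 in red. The triangle is the lower bound of 9.43 for Slfn2, and AA465934 lies at -3.96.

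Other genes with the smallest p did not pass the threshold, and their values are given as measured. The naming rule required groups without overlap, so their separation is no added evidence. Higher in each knockout mouse were Prkar1b, a regulatory subunit of protein kinase A (16.7 against 35.7 CPM), the copper-binding ferroxidase Cp (6.11 against 29.7 CPM), Meis3 (8.72 against 20.3 CPM) and Tmem176a (67.7 against 281 CPM). Lower in each knockout mouse were Ppfia4 (114 against 5.26 CPM), asparagine synthetase Asns (32.5 against 9.47 CPM), Chst3 (3.53 against 0.225 CPM), the sulfatase Sulf2 (189 against 97.8 CPM), Adssl1 (182 against 99.1 CPM), Sgms1 (29.8 against 14.1 CPM), Gpat3 (5.38 against 1.12 CPM) and Rhov (29.6 against 10.9 CPM). Their edgeR adjusted p ranged from 0.14 for Ppfia4 to 0.49 for Rhov.

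Hypoxia-response genes were lower as a list in knockout macrophages. Of 25 tested members 22 had a negative fold change and 3 a positive one, with a median of -0.45, and camera gave an adjusted p of 7.1e-09 (adjusted p = 0.21 with an estimated correlation). No member passed, adjusted over all genes or adjusted over the list alone. The prolyl hydroxylase Egln3 had a log2 fold change of -0.78 (SE 0.22), the oxidoreductase gene Ero1l -0.77 (SE 0.19) and the glucose transporter Slc2a1 -0.45 (SE 0.16), while Vegfa had 0.18 (SE 0.34). The list score was 6.69 ± 0.180 (SD, n = 4) and 6.16 ± 0.197 (SD, n = 3), with an exact permutation p of 0.0571 (adjusted p = 0.42 over all lists). The MC38 tumour and epithelial markers moved with this list, at 2.03 ± 0.487 and 0.938 ± 0.399 mean log2 CPM (exact permutation p = 0.0286, adjusted p = 0.58 over 27 library measures), and so did the neutrophil markers, at 2.54 ± 0.989 and 0.715 ± 0.798.

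Matrix-remodelling proteases were also lower as a list, with 11 of 15 members negative, a median of -1.12 and a camera adjusted p of 7e-04 (adjusted p = 0.21 with an estimated correlation). The macrophage elastase Mmp12 had a log2 fold change of -2.91 (SE 0.86) and Adam8 -1.12 (SE 0.39), whereas Mmp14, the highest expressed, had 0.18 (SE 0.19), and no member passed. The MC38 and neutrophil markers were lower together with this list too, and Mmp8 and Mmp9 belong to both this and the neutrophil list. The score was 6.17 ± 0.407 (SD, n = 4) and 5.10 ± 0.468 (SD, n = 3), beside 2.54 ± 0.989 and 0.715 ± 0.798 for the neutrophil and 2.03 ± 0.487 and 0.938 ± 0.399 for the MC38 markers. Lipid-uptake and lipid-associated macrophage genes had 14 of 21 members negative and a camera adjusted p of 0.019 (adjusted p = 0.56 with an estimated correlation), which was 0.15 without wild-type 2 and 0.33 without knockout 3. In that list Gpnmb had -0.95 (SE 0.29) and Pparg 1.02 (SE 0.34). The glycolysis list had 17 of 20 members negative, a median of -0.16 and a camera adjusted p of 0.027 (adjusted p = 0.56 with an estimated correlation), and it lost its call without wild-type 4 (adjusted p = 0.23) and without knockout 1, 2 or 3 (0.13, 0.094 and 0.063).

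Interferon-stimulated genes were higher as a list. All 28 tested members had a positive fold change, with a median of 0.53 and a camera adjusted p of 3e-12 (adjusted p = 0.31 with an estimated correlation). The largest were Xaf1 at 1.21 (SE 0.30) and Ifi44 at 1.02 (SE 0.32), and Irf7 measured 634 ± 98.9 CPM (SD, n = 4) and 928 ± 336 CPM (SD, n = 3). No member passed, adjusted over all genes or adjusted over the list alone, and the exact permutation p of the score was 0.0571 (adjusted p = 0.42 over all lists). The score of knockout 2, at 7.77, was the highest.

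The T cell and NK cell chemoattractant genes had 9 of 9 tested members positive, a median of 0.75 and a camera adjusted p of 2.9e-05 (adjusted p = 0.26 with an estimated correlation). Cxcl10, a ligand of the chemokine receptor Cxcr3, measured 233 ± 54.7 and 395 ± 58.5 CPM, and Cxcl10 and Ccl5 passed when adjusted over the list alone (adjusted p = 0.042 each), not over all genes. T cell markers did not pass as a list, which was called higher without knockout 1 (camera adjusted p = 1.7e-05) and lower without knockout 3 (4.2e-06). Cd8a measured 0 CPM in knockout 1, 7.24 in knockout 2 and 86.6 in knockout 3, against 0.309 to 9.36 CPM in wild-type mice.

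**Figure D3:**
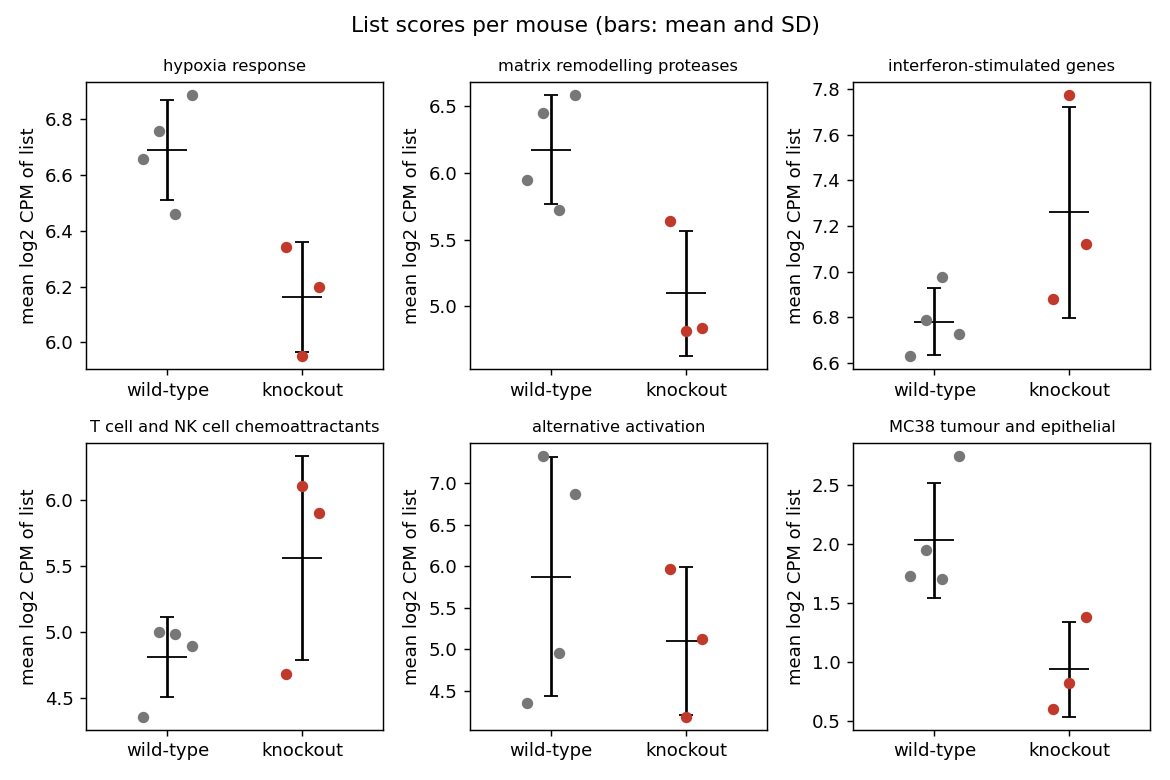
Mean log2 CPM of the genes of 6 lists in each mouse (4 wild-type in grey, 3 knockout in red), with bars for the mean and SD. The hypoxia, matrix protease and MC38 scores of the groups do not overlap, and those of the other lists do.

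MHC class I genes had 13 of 13 members positive with a median of 0.36 (camera adjusted p = 0.0018, and adjusted p = 0.56 with an estimated correlation). MHC class II genes had 9 of 11 positive with a median of 0.54 (camera adjusted p = 0.027, and adjusted p = 0.70 with an estimated correlation). Class I lost its call without wild-type 1 (adjusted p = 0.075) and knockout 2 (0.43), and class II without wild-type 1 (0.36), wild-type 3 (0.13), wild-type 4 (0.051), knockout 2 (0.74) and knockout 3 (0.21). The exact permutation p of the score was 0.34 for class I and 0.54 for class II. Cd74, the invariant chain, measured 13848 ± 7324 and 30013 ± 22254 CPM. The monocyte-derived macrophage markers had 13 of 15 positive (camera adjusted p = 1.3e-04, and adjusted p = 0.47 with an estimated correlation), with Apoe at 14412 ± 4283 and 41748 ± 29147 CPM. Without knockout 2 their adjusted p was 0.12.

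The inflammatory and NF-kB list was called higher (camera adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation) with 12 members positive and 10 negative. Adjusted over the list alone, 4 members were higher, Ccl4, Ccl3, Tnf and Ccl5, and Nos2 was lower. The exact permutation p of the score was 0.69. Il1b measured 2316 ± 1121 and 2110 ± 621 CPM. With the genes at 80 to 86 Mb of chromosome 11 left out, a choice made after the data were seen, the median was -0.042 and the adjusted p 0.96, and the call was also lost without wild-type 1 (0.16), knockout 2 (0.17) or knockout 3 (0.32).

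Alternative-activation genes had 16 of 21 members negative (camera adjusted p = 0.027, and adjusted p = 0.61 with an estimated correlation). The exact permutation p of the score was 0.46. Arg1 measured 3156 ± 2977 and 970 ± 750 CPM, and without wild-type 2, wild-type 4, knockout 2 or knockout 3 the list lost its call, with an adjusted p of up to 0.56. Tissue-resident macrophage markers (8 of 8 negative, adjusted p = 6.9e-04), neutrophil markers (8 of 10 negative, adjusted p = 1.7e-04), MC38 and epithelial markers (6 of 7 negative, adjusted p = 0.0036) and monocyte markers (11 of 14 negative, adjusted p = 0.027) were called lower by camera, each with an adjusted p = 0.26 with an estimated correlation. The monocyte list lost its call without wild-type 2 (0.080), wild-type 3 (0.075), knockout 2 (0.066) or knockout 3 (0.25). The proton-sensing list was called lower through Gpr65, since its median was 0.03 and neither Gpr132 nor Gpr4 passed. It was the 1 list of the 16 called that held with an estimated correlation (adjusted p = 0.037).

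The other 25 of the 41 lists were not called. These included the cAMP-CREB response (12 of 19 positive, camera adjusted p = 0.63), which is the pathway downstream of many G-protein-coupled receptors. They also included cholesterol synthesis (adjusted p = 0.66), lysosome and acidification genes (adjusted p = 0.42), oxidative phosphorylation (adjusted p = 0.34), cell cycle (adjusted p = 0.34), dissociation stress (adjusted p = 0.22), T cell (adjusted p = 0.52) and NK cell markers (adjusted p = 0.45). Some of these depended on single libraries. The cAMP-CREB list was called without knockout 1 (camera adjusted p = 0.011). Of the 7 fits without 1 library, oxidative phosphorylation was called in 3, cell cycle in 2 and cholesterol synthesis in 1.

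By principal components of the 500 most variable genes, knockout 1 stood apart on the component that held 44.2% of the variance, at -68.5, where the other libraries lay between -2.30 and 27.99. It had 940 tested genes at 0 counts, against 51 to 281 in the other libraries. Correlations of log2 CPM were 0.892 to 0.973 within groups and 0.898 to 0.958 between groups.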

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

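Results in this part were chosen after they were seen, except the count of splits for called genes and the test of called genes near Gpr65, which were planned.

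Among 112 sets of 4 wild-type values examined, 8 had a mouse far from the other three, measured as its gap to the nearest mouse over the whole range, and chance flags about 1 in 20. Wild-type 4 stood apart for Asns (0.928), Slc16a3 (0.867) and the glycolysis score (0.869), where it was highest. Wild-type 2 stood apart for Il1b (0.917), the complement and phagocytosis score (0.931), the share of counts in the 10 largest genes (0.859) and the scaling factor (0.877). Wild-type 1 was the lowest in the score of T cell and NK cell chemoattractants (0.843). The 3 knockout mice were too few to examine in this way.

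Of the 35 splits of the 7 libraries, 2 gave at least the 6 genes of the real split, so chance cannot be excluded from the count. The other one grouped wild-type 2, wild-type 4 and knockout 1 and gave 123 genes, which points to a structure of the samples other than genotype. For the gene lists, 10 of 35 splits gave at least the 16 lists of the real one, and the highest of the others gave 21, so chance cannot be excluded there either.

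Slfn2, Slfn5, Slfn9 and AA465934 are neighbours, and with these 4 called genes left out, because the window of 3 Mb around Slfn2 was drawn to hold them, 14 genes in it had an unadjusted p under 0.05, against at most 11 in the other 34 splits. Without the Slfn and Ccl families as well, 8 of 47 genes there did so (17.0%, against 5.26% elsewhere, one-sided Fisher's exact p = 0.0030). Fisher's test takes genes as independent, which neighbours measured in the same mice need not be. The splits were not counted for these 8. A linked sequence difference on chromosome 11 between the groups of mice is therefore no more than a candidate explanation. With the score of interferon-stimulated genes as a covariate the difference in the mean log2 CPM of the 3 Schlafen genes was 4.80 (95% interval 4.33 to 5.27), against 5.08 without it. The 3 genes were chosen for their difference between the groups, and the interferon scores overlapped (6.98 in wild-type 3, 6.88 in knockout 1). A score that differed so little could remove little of the difference, so an interferon response is neither shown nor excluded. A median of 7.38% of words was shared with other Slfn transcripts, and summed Slfn CPM lay above the wild-type range in each knockout mouse. These values argue against reads moved between annotated members as the whole cause. A first form of this test counted words shared with any other gene and was undecided. Those shares were 4.27%, 11.1% and 11.9% for Slfn2, Slfn5 and Slfn9. Reads dropped for matching several genes would not show in the sum and were not examined. Near Gpr65 itself 0 of 98 tested genes within 10 Mb were called (Fisher's exact p = 1), which allows up to 3.06% against 0.031% elsewhere, and 9 had an unadjusted p under 0.05 (9.18%, against 5.34% elsewhere, one-sided Fisher's exact p = 0.079), so flanking DNA there stays open. An effect of Gpr65 loss on the Schlafen genes stays open as well, and whether the mice differ in sequence there was not examined, because the counts hold no sequence. The breeding of the knockout mice is not given in the sources used here. A difference in background between the groups was not examined for Wdfy1 either, so its cause stays open too.

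The hypoxia score was lower by 0.527 in knockout mice. With the neutrophil score as a covariate the difference was -0.206 (95% interval -0.548 to 0.137), below 0.5 of its size. This interval holds both 0 and the difference without the covariate. The neutrophil score also differed between the groups, so carry-over of neutrophils is neither shown nor excluded. The sort for F4/80 would remove such cells. S100a8 and S100a9 measured 7.86 and 7.13 CPM in wild-type mice and 2.31 and 1.85 CPM in knockout mice. Of 10 tested neutrophil markers 8 had a negative fold change, and Csf3r went the other way (75.2 against 127 CPM). The sort for CD45 would remove MC38 tumour and epithelial cells, whose score held 7 tested genes. Among these, Krt18 measured 4.42 CPM in wild-type 4 and 0.540 to 0.915 CPM in wild-type 1 to 3. Krt8, left out by the filter, measured 2.81 CPM in wild-type 4 and 0 in wild-type 1 to 3. With the MC38 score as a covariate the difference in the hypoxia score was -0.316 (95% interval -0.993 to 0.361). This is too wide in 7 mice to exclude carry-over of tumour cells. Genotype stays open as a biological explanation.

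Knockout 1 lay 2.45 times as far out on the main component as the next library. Without the 851 genes that followed the T cell score it lay 2.92 times as far out, which argues against fewer T and NK cell transcripts as the whole cause. Its deviation exceeded that of the next library 1.53-fold among weakly and 1.05-fold among strongly expressed genes, a ratio of 1.47 that fell short of the 1.5 set for fewer captured RNA molecules, so that explanation stays open. No biological explanation was tested.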

How the results depend on the processing

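Counts of called genes moved with the tool and the filter. DESeq2 called 114 genes (43 higher, 71 lower), limma voom with library weights 10 (4 lower), and edgeR without the filter 11 (7 higher, 4 lower). DESeq2 size factors and upper-quartile factors left 1 gene lower. Leaving out 1 library gave 3 to 14 genes, 2 to 9 higher and 1 to 5 lower, with 14 when knockout 1 was left out. The cause was not tested, except that the unfiltered fit tested 29002 genes. Gpr65 passed under all 16 alternatives, at -6.78 to -6.45 on the log2 scale, Slfn9 and Wdfy1 under 15, Slfn2 under 14, Slfn5 under 11 and AA465934 under 5. AA465934 missed the threshold under the 3 other scalings (adjusted p of 0.053 to 0.066; with library size alone Ppfia4 was called in its place) and by limma voom (0.11). The 4 higher genes of the main fit passed in each of the 3 other scalings, and library size alone shifted the median of all genes by -0.107. Over the 66 named genes besides Gpr65, 48 of 1054 values, from 20 genes that were not called, changed sign.

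The labels do not say that mouse numbers pair the mice. Same-numbered mice had deviations from their group means correlated at 0.066, 0.051 and 0.088. Differently numbered mice had -0.19 to 0.095, and so few pairs cannot exclude a pairing. With the replicate block 1 gene was called, 0 higher and 1 lower (Gpr65), and 15 lists.

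Of 16 lists called, 1 held with an estimated correlation and 0 by fry, while leaving out 1 library gave 13 to 25. Without knockout 3 the T cell and NK cell lists had medians of -1.22 and -1.23 and were called lower (adjusted p = 4.2e-06 and 0.014), while without knockout 1 both were called higher (1.7e-05 and 0.011), and over the libraries left out these medians reached 1.47 and 1.72. Without the chromosome 11 genes, an alternative chosen after the data were seen, the median of the inflammatory list was -0.042. Without Gpr65, also chosen then, 15 lists were called, because the proton-sensing list was too short to test. The number of library measures at the smallest exact p was 1, and 0 to 7 without 1 library. At this depth and number of mice 9 of 100 simulated 2-fold changes were recovered.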

Other observations

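The score of the alternative-activation list was 7.33 and 6.87 mean log2 CPM in wild-type 2 and wild-type 4 and 4.19 to 5.97 in the other mice. In that list Ccl24, an eosinophil-attracting chemokine, measured 6.32, 2411, 27.3 and 998 CPM in wild-type mice 1 to 4 and 346, 11.5 and 42.3 CPM in knockout mice 1 to 3. Chil3, a chitinase-like protein, measured 16.6, 3241, 30.6 and 707 CPM in the wild-type mice and 152, 10.3 and 9.48 CPM in the knockout mice. Retnla reached 250 and 168 CPM in wild-type 2 and wild-type 4 and at most 4.45 CPM in the other mice. The coagulation factor gene F10 measured 367 and 174 CPM in those mice and 4.72 to 36.9 CPM in the others, and Arg1 6421 and 4939 CPM against 233 to 1733 CPM. Scores of marker lists of other cell types moved with these values. The mean log2 CPM of 3 eosinophil markers was 3.61 and 1.98 in wild-type 2 and wild-type 4 and at most 0.41 in the other mice, and that of the neutrophil markers was 3.54 and 3.20 against 0.091 to 1.92. The eosinophil score may rest largely on 1 gene, Alox15. Its log2 fold change between the groups was -5.87 (SE 1.53), against a median of -1.70 over the 3 markers. Whether eosinophils were present was not tested. Among the other members of the list, Mrc1 measured 498 and 394 CPM in wild-type 2 and wild-type 4 and 104 to 236 CPM in the other mice. Tgm2 measured 1084 CPM in each of those 2 mice, 367 and 603 CPM in wild-type 1 and 3, and 500, 576 and 1322 CPM in knockout mice 1 to 3. The log2 fold change between the groups was 0.02 (SE 0.19) for Il4ra and 0.03 (SE 0.45) for Tgm2, but 16 of 21 members were negative, with a median of -0.77. A fold change between the groups does not show whether a member follows wild-type 2 and wild-type 4. The genes and mice named here were chosen after their values were seen, and the labels give no factor that separates these mice.

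Cytotoxic lymphocyte transcripts were highest in knockout 3, with Gzmb at 262 CPM and Nkg7 at 222 CPM, against 6.22 and 9.02 CPM in knockout 1. In the wild-type mice Gzmb measured 14.0 to 82.5 CPM and Nkg7 9.19 to 54.3 CPM. Fn1, the gene of fibronectin, measured 2194 ± 667 CPM (SD, n = 4) in wild-type and 530 ± 496 CPM (SD, n = 3) in knockout mice, where the values were 1102, 220 and 267 CPM, and it did not pass (edgeR adjusted p = 0.74), although it was called without knockout 1 and by limma voom.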
